A study of Mus musculus with 12 samples.

How the data were processed

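Per the labels, mice carried 4 transgenes (a keratin 5 driven tTA, a tTA-responsive H2B-GFP, a keratin 14 driven CreER and a tdTomato reporter at Rosa26), received doxycycline at 1 g/kg of food for 2 weeks and tamoxifen at 75 mg/kg once, and were killed 1 week later at second telogen. The labels also give sorting by flow cytometry, RNA by RNeasy micro, and 5 ng of RNA amplified with the NuGEN Ovation Pico WTA system and labelled with the Encore Biotin Module. Sorting gates, the summarisation software and its parameters are not given in the sources used here. The labels do not say whether the samples are separate animals, so the p-values measure only the spread between these samples. The readings basal, spinous and granular layer and label-retaining cell, and the origin of Dlx1 and Slc1a3 as the study's own markers, come from knowledge of the study and not from the labels. Gene lists were written from general knowledge of skin biology.

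The deposited values are intensity values, which the authors scaled to a 2% trimmed mean of 500.0 on every array, as recomputed here from all probe sets. The design assumed log2 values, while the deposited values are linear, with a floor at 1 and a maximum of 71928.6, so log2 was taken with nothing added. Between 1.07% and 2.24% of probe sets per array sat at the floor of 1. Of 45101 probe sets, 64 are controls, 34945 map to 1 gene, 932 to several and 9160 to none by the platform annotation. Only probe sets with 1 gene were used, and for the 9010 genes with several the probe set of highest mean was kept, giving 18193 genes, 1543 of them by a probe set marked as possibly cross-hybridising. Symbols were looked up by gene identifier in a RefSeq table of assembly GRCm38.p6, which was used for names alone and changed 0 of 34754 symbols.

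Background was taken per array as the 95th percentile of 27 probe sets for bacterial transcripts that are not expected in the sample, 22.4 to 42.5 intensity units. Where 1 side of a comparison was never above this floor the difference is given as a lower bound ("at least"), and where neither side was ever above it, or that bound fell under 1, no fold is given. The size is also left open where only some arrays of a side were above the floor and its mean was not, or where 1 of 2 groups averaged in a side was never above it. Among the genes of largest change the absence of a bound applied to Obox6, Tmprss11g and Peg10 in BL, Apof and Tmc2 in SL, Trpv1, Btbd18 and Ly6f in SL vs BL, and Plxna4os1 and Zfp354b in GL vs SL. The 6 BioB probe sets served only to compare array sets. The pair of array sets was read from their signal after the data were seen, and so was the Y-linked signal.

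Differential expression used limma 3.58.1 in R 4.3.3, with 1 linear model of 5 group means over all 12 arrays, empirical Bayes moderation with a mean-variance trend, and Benjamini-Hochberg adjustment over 18193 genes at 0.05. Errors beside log2 differences are moderated standard errors. SL vs BL compares the mean of both SL groups with the mean of both BL groups, and GL vs SL compares GL with the mean of both SL groups. The interaction is the SL label effect minus the BL label effect. These comparisons, the gene lists, the threshold and the alternatives were fixed before the data were examined.

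The 28 lists were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, adjusting over the lists of each comparison. A count "over all genes" uses the adjustment over 18193 genes, and "adjusted over the list alone" adjusts within that list. Genes are named by a rule fixed in advance: the 12 largest changes per direction among called genes whose samples do not overlap, up to 4 members of smallest p in each list described, and 14 set genes (Dlx1, Slc1a3, Aspm, Krt5, Krt14, Krt15, Krt1, Krt10, Ivl, Lor, Flg, Mki67, Trp63 and Itga6). Genes outside the rule are said to be named afterwards.

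Recovery was measured by adding changes to 200 simulated genes. At 2-fold the share recovered was 18% in BL, 19% in SL, 34% between layers and 18% for GL, and at 4-fold 50%, 48%, 61% and 52%, with 2.78% to 8.65% of calls false. In the upper 50% of genes by mean signal, 4-fold recovery was 93.6%, 88.5%, 100% and 98%. The simulated noise was independent between genes and held no array-set or sex-linked difference. The false share therefore does not cover the array set that coincides with the SL groups. Bootstrap intervals are 95% over 2000 draws of genes on the same arrays. They treat genes as independent and hold no spread between arrays or animals. Figures used Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3. Scanner-level data were not used here.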

Results

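Keratinocyte fractions were sorted from mouse back skin by flow cytometry, with gates that are not given. The mouse line carries a histone H2B-GFP label that is repressed by doxycycline and lost as cells divide. The labels abbreviate the fractions as BL, SL and GL, read here as basal, spinous and granular layer from what is known of the study. LRC is read as label-retaining cell, the infrequently dividing fraction. The 12 arrays comprise 3 BL LRC, 3 BL non-LRC, 2 SL LRC, 2 SL non-LRC and 2 GL samples. Each array reports 18193 genes, of which 68.5% to 78.4% lay above that array's background floor, and replicates of a group correlated at r = 0.908 to 0.917. The first principal component, with 40.2% of the variance, ran from BL LRC 1 to GL 1, and the second, with 20.8%, placed LRC and non-LRC arrays apart in both layers.

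The arrays fall into 2 sets by a bacterial control added to every hybridisation. BioB signal averaged 490 ± 30.7 intensity units (SD, n = 4) on BL LRC 1, BL non-LRC 1, SL non-LRC 1 and SL non-LRC 2, and 3299 ± 299 units (SD, n = 8) on the others. The sets are balanced in BL, whereas in SL they coincide with LRC and non-LRC. The Y-linked genes Eif2s3y, Kdm5d and Uty were all above background on 10 arrays and all at or under it on 2, BL LRC 1 and BL non-LRC 1. In BL the low-BioB set therefore also differs in this sex-linked signal, while every SL and GL array carries it. The 3' minus 5' log2 difference of the Actb control probe sets, a measure of RNA quality, averaged -0.060 in GL and -0.067 in SL non-LRC. It averaged -0.19 in SL LRC, -0.20 in BL LRC and -0.20 in BL non-LRC. For Gapdh this difference was 1.22 on GL 1 and 0.68 on GL 2.

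**Figure D1:**
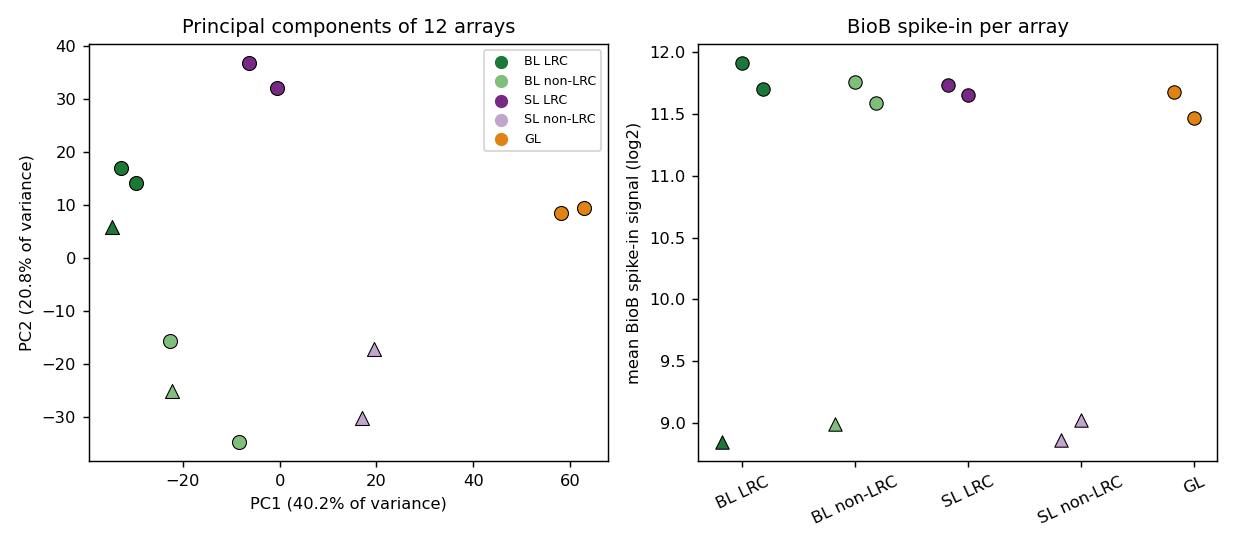
Left, the first (40.2%) against the second (20.8%) principal component of the upper 50% of genes by mean signal, with 1 point per array, colours for groups and triangles for low-BioB arrays. Right, mean BioB signal per array in log2 units, 8.85 to 9.03 in the low set and 11.5 to 11.9 in the high set.

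Label-retaining basal cells carried far less of the sebaceous and infundibular transcripts than basal cells that had lost the label. Mgst1, an abundant sebaceous transcript, fell by 4.85 ± 0.49 log2 units (SE, n = 3 and 3, adjusted p = 3.54e-05). Krt79, a keratin of the infundibulum, fell by 2.72 ± 0.20 (adjusted p = 2.66e-06). Pparg, a regulator of sebocyte lipid metabolism, was at least 19.4-fold lower (adjusted p = 0.00109). In the other direction Igfbp3, whose product binds insulin-like growth factors, rose by 3.04 ± 0.61 (adjusted p = 0.015), a call lost in 4 of 6 fits that each leave out 1 array (highest adjusted p = 0.0897). In all, 56 genes were higher and 223 lower in BL LRCs, 79.9% of the called genes being lower, and 2026 genes had an unadjusted p under 0.05.

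The largest decreases in BL LRCs also took in Avpr1a, a vasopressin receptor (-5.99 ± 0.79, adjusted p = 0.000395), Cers4, a ceramide synthase (-5.33 ± 0.86), and Akr1c18 (-4.79 ± 0.54). Cidea, a lipid-droplet gene, was lower too (adjusted p = 0.00444), by an amount left open because only 1 of 3 BL LRC arrays was above background. Lama4 was at least 15.1-fold lower and Dusp4 at least 10.3-fold lower. Kcnk1 (at least 15.2-fold), Cd36 (at least 14.5-fold) and Lcn2 (at least 3.33-fold) were lower as well, with a highest adjusted p of 0.0794, 0.149 and 0.274 in that order when 1 array was left out. Among increases, Grtp1 (2.37 ± 0.38, adjusted p = 0.00228), the glycolytic regulator Pfkfb3 (2.14 ± 0.38) and the chemokine receptor Ccr4 (2.00 ± 0.35) came from values above background on both sides. Npr3, a natriuretic peptide receptor, and Rgs16 were at least 5.94-fold and 4.34-fold higher, with highest adjusted p of 0.078 and 0.0911 when 1 array was left out.

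As gene groups, infundibulum and sebaceous markers had 12 of 15 members lower (median -1.86), Mgst1, Krt79, Sostdc1 and Defb6 among them, and this list alone kept its call with an estimated correlation between genes (adjusted p = 0.00607). Mitosis genes had a median of -0.997, with Ube2c (-1.39 ± 0.23, adjusted p = 0.00324), Cdc20 and Ccnb2 lower, 3 of 30 over all genes, and 13 lower and 1 higher adjusted over the list alone (adjusted p = 0.0711 with an estimated correlation). Mki67 was at -0.84 ± 0.21 (adjusted p = 0.0559, and 0.021 with the replicate block given below). Aspm, a spindle gene, was at -0.91 ± 0.37 (adjusted p = 0.347). DNA replication genes had 0 of 31 called and a median of 0.03. Spinous genes had 5 of 23 higher over all genes (median 0.44) and 14 higher and 1 lower adjusted over the list alone (adjusted p = 0.144 with an estimated correlation), with Krt77 at 0.58 ± 0.11 and Mt4 at 1.57 ± 0.36. Centring arrays on their medians left 0 of these 23 called, with a median of 0.20. Krt10, the suprabasal keratin, rose by 0.52 ± 0.11 (adjusted p = 0.0214), a call lost in 4 of 6 fits without 1 array.

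Bulge genes had 3 of 17 lower, Sox9 (-2.04 ± 0.19, adjusted p = 1.67e-05), Foxc1 (-3.16 ± 0.32) and Vdr (adjusted p of the list 0.0766 with an estimated correlation). Oxidative phosphorylation genes were below 0 in 31 of 31 members with a median of -0.24 and 1 called, Ndufa4 (adjusted p = 0.0527 with an estimated correlation). A further set of lists passed the preset test and not the estimated correlation: wound genes with Fst and Gjb2 lower and fibroblast genes with Mgp lower (each adjusted p = 0.153), cholesterol synthesis with 0 of 19 called and a median of -0.43, and granular genes with 1 of 34 called (each adjusted p = 0.355). That gene, Nccrp1 (adjusted p = 0.0498), lost its call in 6 of 6 fits without 1 array (highest 0.179) and with the array-set term (0.0556). The epidermal keratins Krt5 (0.24 ± 0.13), Krt14 (0.096 ± 0.10), Krt15 (0.18 ± 0.13) and Krt1 (0.58 ± 0.16) had no adjusted p under 0.05, nor did Trp63 (0.27 ± 0.14) and Itga6 (0.01 ± 0.13). Dlx1 (1.32 ± 0.73, adjusted p = 0.543) and Slc1a3 (-0.92 ± 0.58, adjusted p = 0.612), the marker pair the study chose from these samples, did not pass either.

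The BL counts depend on scaling and on single arrays. Centring arrays on their medians moved the share of lower genes from 79.9% to 95.1% and the median over all genes from 0.046 to -0.19 log2 units. The 279 called genes became 169 without BL LRC 2, 149 without BL LRC 3 and 131 without BL non-LRC 3. With the 4 high-BioB arrays alone 136 genes passed, 125 of them among the 279. All 279 kept their sign, which could not turn, since none of these genes overlapped between the 2 groups.

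Spinous LRCs differed from spinous non-LRCs by lower cell-cycle transcripts. Mki67, the proliferation marker, fell by 2.09 ± 0.25 log2 units (SE, n = 2 and 2, adjusted p = 0.000219), and Mcm5, a subunit of the replicative helicase, fell by 1.74 ± 0.23 (adjusted p = 0.000456). Krt1, an early differentiation keratin, rose by 1.12 ± 0.20 (adjusted p = 0.00372), a call lost with the array-set term given below (adjusted p = 0.0829) and in 2 of 4 fits without 1 array (highest 0.0981), and Igfbp3 rose by 4.77 ± 0.75 (adjusted p = 0.00153). Over all genes 271 were higher and 492 lower (64.5% lower), and 3070 had an unadjusted p under 0.05. The 2 array sets coincide with the 2 groups here, so label retention and array set cannot be told apart from SL arrays alone. A set term estimated through BL left 320 genes past the threshold, 270 of them among the 763, with all 763 keeping their sign. The median size of those changes moved from 1.67 to 1.62 while their median SE rose from 0.328 to 0.417.

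Mitosis genes had 11 lower and 1 higher (Ttk, 2.95 ± 0.41) of 30 over all genes, a median of -1.62, and 24 lower and 1 higher adjusted over the list alone, with an adjusted p of 0.0425 with an estimated correlation. Aspm fell by 2.29 ± 0.45 (adjusted p = 0.00787, and 0.056 with the set term). DNA replication genes had 10 of 31 lower (median -0.80), with Mcm5, Cdt1, Gins2 and Rrm2 among them. Infundibulum and sebaceous genes had 10 of 15 lower (median -2.15), such as Plet1 (-2.15 ± 0.24, adjusted p = 0.000119), Lrig1 (-1.76 ± 0.21), Gata6 (-3.39 ± 0.41) and Mgst1 (-4.34 ± 0.59). Bulge genes had 6 of 17 lower, among them Sox9 (-2.41 ± 0.23) and Foxc1 (-3.02 ± 0.39), and 1 higher, Krt24 (2.86 ± 0.67), named after its value was seen. The replication, sebaceous and bulge lists each had an adjusted p of 0.0177 with an estimated correlation. With the set term, which has larger errors, 4 mitosis genes were called lower and 1 higher (median -1.92), 2 replication genes lower (-0.63), 8 sebaceous and infundibular genes lower (-2.48), and 5 bulge genes lower and 1 higher (-0.93).

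Spinous genes had 7 of 23 higher (median 0.58, adjusted p = 0.119 with an estimated correlation), including Them5 (1.90 ± 0.26) and Mt4 (2.85 ± 0.44), and lipid barrier genes had 4 of 24 higher and 1 lower, Elovl4 at 1.73 ± 0.26 and Fa2h at -3.40 (adjusted p = 0.0792 with an estimated correlation). Granular genes had 3 of 34 higher and 2 lower, with a median of -0.16, and did not pass as a list (adjusted p = 0.924). Krt10 was 0.56 ± 0.14 higher (adjusted p = 0.0262, and 0.151 with the set term), a call lost in 4 of 4 fits without 1 array. Wound genes had 5 of 19 lower, Gjb2 (-3.33 ± 0.50), Krt6a (-2.68 ± 0.48), Fst and Sprr1a among them (adjusted p = 0.119 with an estimated correlation). Oxidative phosphorylation genes had 3 of 31 lower (median -0.32, adjusted p = 0.0565 with an estimated correlation). Myeloid genes had 4 of 16 lower, among them Csf1r, H2-Aa and Cd74 (adjusted p = 0.267 with an estimated correlation), and melanocyte genes 2 of 12, Dct and Tyrp1 (adjusted p = 0.152 with an estimated correlation and 0.227 with the set term). Ribosomal protein genes had 0 of 24 called and a median of 0.26 (adjusted p = 0.457 with an estimated correlation and 0.227 with the set term). With the set term the medians stayed near these for spinous (0.50, 1 higher), lipid barrier (0.72, 1 higher and 2 lower), wound (-0.54, 4 lower) and oxidative phosphorylation genes (-0.323, 1 lower). They moved from -1.19 to -0.63 for myeloid genes (1 lower) and from -1.21 to -0.070 for melanocyte genes (0 called).

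Among the largest SL decreases, Il18r1 was at least 4.72-fold lower (adjusted p = 0.000523, and 0.0045 with the set term) and Csf1r at least 9.91-fold lower (adjusted p = 0.00112, and 0.0174 with the set term). Avpr1a was at -5.68 ± 0.96 (adjusted p = 0.00254, and 0.0622 with the set term). Gprin3, Cdo1 and Pkdcc were at least 7.43-fold, 13.9-fold and 11.1-fold lower and lost their calls with the set term (adjusted p = 0.0633, 0.103 and 0.167). Of the largest increases Ccr4 (3.12 ± 0.43), Sema3d (3.49 ± 0.55), Dab1 (at least 10.7-fold) and Zc2hc1c (at least 6.54-fold) stayed past the threshold with the set term (adjusted p = 0.00336, 0.0316, 0.0045 and 0.0166), whereas Serpinb12, B4galnt2, C8b and Mal did not (adjusted p = 0.119, 0.208, 0.135 and 0.0647). Slc1a3, not above background on either SL LRC array, had an adjusted p of 0.0563, and Dlx1, above background on 1 array of each fraction, an adjusted p of 0.437. The direction of Slc1a3 turned under quantile normalisation, where the probe set of highest mean was chosen again and may be another one. Leaving out SL LRC 1, SL LRC 2, SL non-LRC 1 or SL non-LRC 2 gave 300, 410, 481 and 209 called genes in place of 763. Centring on medians moved the share of lower genes from 64.5% to 81.8% and the all-gene median to -0.14.

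LRCs differed from non-LRCs in many of the same genes in both layers. Of the called genes, 34 were higher in LRCs of both layers and 155 lower in both, and 0 had opposite calls. Independent calls over all 18193 genes, those under background included, would give 0.834 and 6.03. Of the 279 genes called in BL, 97.8% had the same sign in SL, and 93.7% of the 763 called in SL had the same sign in BL. Mgst1, Pparg, Sox9, Foxc1 and Avpr1a belong to the lower group, and Igfbp3, Ccr4 and Mt4 to the higher group. The 2 effects correlated at r = 0.52 over 12982 genes above background, and genes are not independent replicates. A test of the difference between the 2 label effects (SL minus BL, limma interaction term) called 0 genes, with 1291 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0948. Leaving out BL LRC 3, BL non-LRC 1, BL non-LRC 3, SL LRC 2 or SL non-LRC 2 gave 1, 3, 6, 1 and 1 genes, Tpm2, Tpm1 and Ctsl among them, named after their values were seen.

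**Figure D2:**
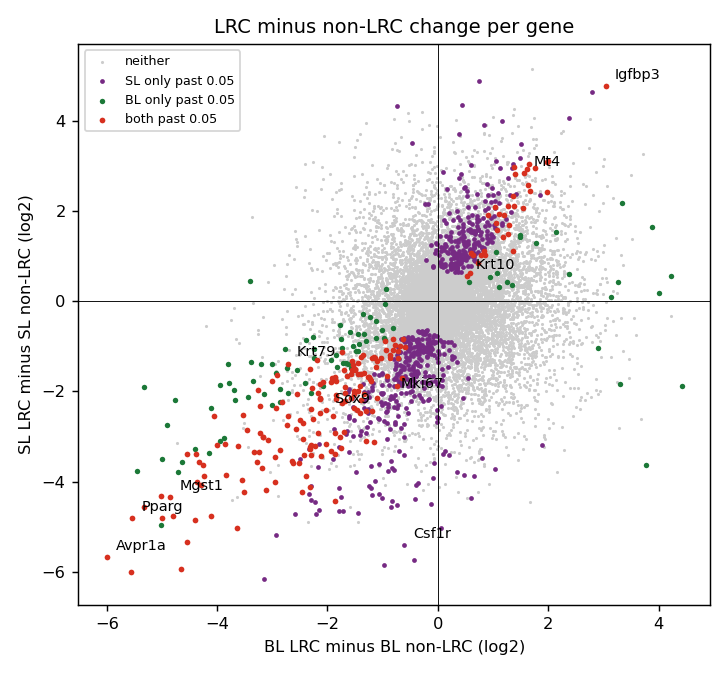
Each point is a gene, with its LRC minus non-LRC log2 difference in BL across and in SL upward, coloured by the comparison in which it passed the threshold. The 34 genes higher and 155 lower in both lie on opposite sides of the origin, and 0 genes were called in opposite directions.

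Spinous cells carried more of the late differentiation programme and less of the adhesion and replication programmes than basal cells. Klk7, a protease of the outer epidermis, rose by 2.96 ± 0.20 log2 units (SE, n = 4 and 6, adjusted p = 2.6e-07), Dsc1, a desmosomal cadherin, by 2.51 ± 0.20 (adjusted p = 1.25e-06) and Ivl, a cornified-envelope precursor, by 1.94 ± 0.31 (adjusted p = 0.00114). Itga6, the hemidesmosomal integrin of basal cells, fell by 0.82 ± 0.10 (adjusted p = 0.000132), and Mcm3 fell by 1.496 ± 0.13 (adjusted p = 4.66e-06). In all 515 genes were higher and 400 lower (43.7% lower), with 2880 at an unadjusted p under 0.05.

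Granular and cornified-envelope genes had 17 of 34 higher and 1 lower, Tgm3 (-1.11 ± 0.21), with a median of 1.81. Spinous genes had 15 of 23 higher (median 0.92, with Sbsn, Grhl1 and Ovol1) and lipid barrier genes 9 of 24 (median 0.81, with Acer1, Elovl4 and Lipm). DNA replication genes had 19 of 31 lower, 28 adjusted over the list alone, and 31 of 31 below 0 (median -1.03). Basal genes had 13 of 23 lower (median -0.67, with Cdh3 at -1.19 ± 0.17) and basement membrane genes 14 of 24 (median -0.73, with Itgb1 and Lamb3), 2 lists that share 9 members. With an estimated correlation these 6 lists had adjusted p of 0.00512 (granular and lipid), 0.0104 (spinous), 0.000865 (replication) and 0.00762 (basal and basement membrane). Krt5 (-0.30 ± 0.10, adjusted p = 0.108), Krt14 (adjusted p = 0.153) and Krt15 (adjusted p = 0.309) did not pass, nor did Krt1 (0.18 ± 0.13, adjusted p = 0.593) and Krt10 (0.16 ± 0.09, adjusted p = 0.429).

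Follicular and stress-associated genes were also higher in SL. Hair shaft and inner root sheath genes had 6 of 16 higher (median 1.68), including Krt25 (2.94 ± 0.40), Krt71, Hoxc13 and Krt27 (at least 5.28-fold, adjusted p = 0.00153). Bulge genes had 6 of 17 higher, such as Lhx2 (2.10 ± 0.19), and 1 lower, Postn (-1.53), and infundibulum and sebaceous genes 5 of 15, with Krt79 at 2.56 ± 0.16 (adjusted p = 1.5e-07). Wound genes had 5 of 19 higher, with Sprr1a at 3.004 ± 0.19 and Krt6a at 3.15 ± 0.31, and immediate early genes 6 of 24, with Egr2 at 1.71 ± 0.20, Zfp36, Egr1 and Jun. Their adjusted p with an estimated correlation were 0.00762, 0.027, 0.0221, 0.00884 and 0.0104. Cholesterol synthesis genes had 5 of 19 higher, such as Dhcr7 (adjusted p = 0.113 with an estimated correlation), and mitosis genes 2 of 30 lower, Ect2 and Anln (adjusted p = 0.112 with an estimated correlation).

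The largest increases from BL to SL included Teddm3 (4.06 ± 0.34, adjusted p = 2.71e-06), the tight-junction gene Cldn4 (adjusted p = 0.000641) and Flg (at least 2.06-fold, adjusted p = 0.00526), where Cldn4 was above background on only 2 of 6 BL arrays and its size is left open. The largest decreases included Cort (at least 5.72-fold, adjusted p = 0.000219), the neurotrophin receptor Ntrk2 (-2.47 ± 0.38), Chek1 (-2.25 ± 0.40) and Ssh1 (-2.24 ± 0.26, adjusted p = 5.92e-05). E2f7, lower at an adjusted p of 0.0202 and above background on only 1 of 4 SL arrays, reached 0.115 without SL LRC 1. Within LRCs the SL minus BL comparison called 512 genes and within non-LRCs 283. Of these, 111 were higher in both and 28 lower in both, 1 gene (Tpm2, -0.89 in LRCs and 1.08 in non-LRCs) had opposite calls, and the 2 layer effects correlated at r = 0.38. The high-BioB arrays alone, SL LRC against BL LRC, gave 282 genes, and leaving out SL non-LRC 1 or SL LRC 2 gave 529 and 605. Centring on medians moved the share of lower genes from 43.7% to 30.1%.

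The granular fraction carried strong immune-cell signal beside lower hemidesmosomal genes. Fcer1g, a receptor subunit of myeloid cells, rose by 4.55 ± 0.46 log2 units over SL (SE, n = 2 and 4, adjusted p = 1.12e-05), and Cd3g, a T-cell receptor subunit, rose by 4.25 ± 0.40 (adjusted p = 6.44e-06). Col17a1, a hemidesmosomal collagen, fell by 1.98 ± 0.15 (adjusted p = 1.42e-06) and Itga6 by 0.94 ± 0.14 (adjusted p = 0.000381). Lor, the major cornified-envelope protein gene, rose by 1.92 ± 0.56 (adjusted p = 0.0422), which became 0.481 without GL 1 and 0.163 with the array-set term. Over all genes 799 were higher and 711 lower (47.1% lower), with 3784 at an unadjusted p under 0.05. The high-BioB arrays alone, GL against SL LRC and so another comparison, gave 1677 genes. With the array-set term GL vs SL gave 1144 genes, 1014 of them among the 1510 called without it.

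Myeloid genes had 13 of 16 higher (median 3.80, adjusted p = 0.0273 with an estimated correlation), with H2-Aa at 4.10 ± 0.44, Mfge8 and Laptm5, and T-cell genes 10 of 15 (median 4.02, adjusted p = 0.0555 with an estimated correlation), with Ptprc, Nkg7 and Cd3e. Melanocyte genes had 2 of 12 higher, Dct (3.57 ± 0.50) and Tyrp1, and fibroblast genes 1 of 18, Vim (3.78 ± 0.43), each with an adjusted p of 0.0736 with an estimated correlation. The largest increases included Gpr171 (at least 13.3-fold), S100b (at least 20.2-fold, adjusted p = 0.000669), Csf1r (adjusted p = 7.5e-05, by an amount left open), Cmah (5.63 ± 0.58) and Ltc4s (at least 9.04-fold, with an adjusted p of 0.0982 without GL 1). Bulge genes had 6 of 17 higher (median 1.36, adjusted p = 0.0205 with an estimated correlation), with Lhx2 at 3.14 ± 0.26, and wound genes 6 of 19 (adjusted p = 0.0263 with an estimated correlation), with Gjb2 at 4.45 ± 0.44. Hair shaft genes had 4 of 16 higher, such as Hoxc13 (3.43 ± 0.41) and Krt28 (adjusted p = 0.0555 with an estimated correlation).

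Basal genes had 13 of 23 lower and 2 higher, Cdh3 (1.35 ± 0.22) and Thbs1 (0.94 ± 0.27), named after their values were seen (adjusted p = 0.0584 with an estimated correlation). Basement membrane genes had 13 of 24 lower and 1 higher, Fras1 (adjusted p = 0.0420), also named afterwards and near background in SL, with Col4a1 at -2.85 ± 0.26 and Col7a1 at -2.48 (adjusted p = 0.0456 with an estimated correlation). DNA replication genes had 11 of 31 lower, such as Mcm3 and Cdt1 (-1.91 ± 0.20, adjusted p of the list 0.0263 with an estimated correlation), and mitosis genes 8 of 30 lower, such as Prc1 and Cenpf (adjusted p = 0.0736 with an estimated correlation). Mcm3 turned to 0.29 with the probe set of highest variance. The mitosis median was -1.80 against SL non-LRC and 0.022 against SL LRC, and that of replication -1.12 and -0.39, splits of the SL side made after the result was seen. Granular genes had 6 of 34 higher, Klk7 (1.88 ± 0.27), Cdsn and Klk5 among them, and Tgm3 lower at -1.96 ± 0.29 (median 1.13, adjusted p = 0.0641 with an estimated correlation). BMP and TGF-beta targets had 4 of 17 higher, such as Id4 and Id2, and 2 lower, Tgfbi and Bmp4 (adjusted p = 0.0555 with an estimated correlation). Oxidative phosphorylation genes had 3 of 31 lower (adjusted p = 0.0714 with an estimated correlation), cholesterol synthesis 3 of 19 lower with Hmgcs1 (0.296), ribosomal proteins 1 of 24 lower, Rpl14 (0.407), cell cycle inhibitors 3 of 19 higher, Gas1, Ndrg1 and Btg2 (0.0968), and glycolysis 2 higher and 2 lower of 15, Pfkp, Hk2, Pgam1 and Hk1 (0.305).

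Of the largest decreases toward GL, Ackr3, a chemokine scavenger, was at -4.00 ± 0.27 (adjusted p = 3.15e-07), the alarmin Il33 at -3.80 ± 0.36 (adjusted p = 6.08e-06), Gdnf at least 5.47-fold lower (adjusted p = 4.69e-05) and Avpr1a lower at an adjusted p of 0.0021, above background on 1 of 2 GL arrays. Krt15 fell by 0.61 ± 0.14 (adjusted p = 0.0114, and 0.154 without GL 1), whereas Krt14 (0.32, adjusted p = 0.0871), Flg (2.67 ± 0.90, adjusted p = 0.0825), Ivl (1.03 ± 0.42, adjusted p = 0.164) and Mki67 (-0.72 ± 0.22, adjusted p = 0.0523) did not pass. The basal genes Krt5 (0.075 ± 0.13, adjusted p = 0.824) and Trp63 (-0.21 ± 0.15, adjusted p = 0.476) did not pass in GL vs SL. Neither did the suprabasal keratins Krt1 (-0.38 ± 0.17, adjusted p = 0.218) and Krt10 (-0.22 ± 0.12, adjusted p = 0.319). Krt5 averaged 14.4 in GL and 14.3 in SL. Mki67 averaged 10.2 in GL, 9.84 in SL LRC and 11.9 in SL non-LRC, so its lower value in GL rests on the SL non-LRC arrays. The count of 1510 became 575 without GL 1 and 890 without GL 2, with 1 GL array left in each case. Centring on medians moved the share of lower genes from 47.1% to 59.99% and the all-gene median to -0.17. The SL arrays enter both layer comparisons, so the 2 are not compared with each other.

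**Figure D3:**
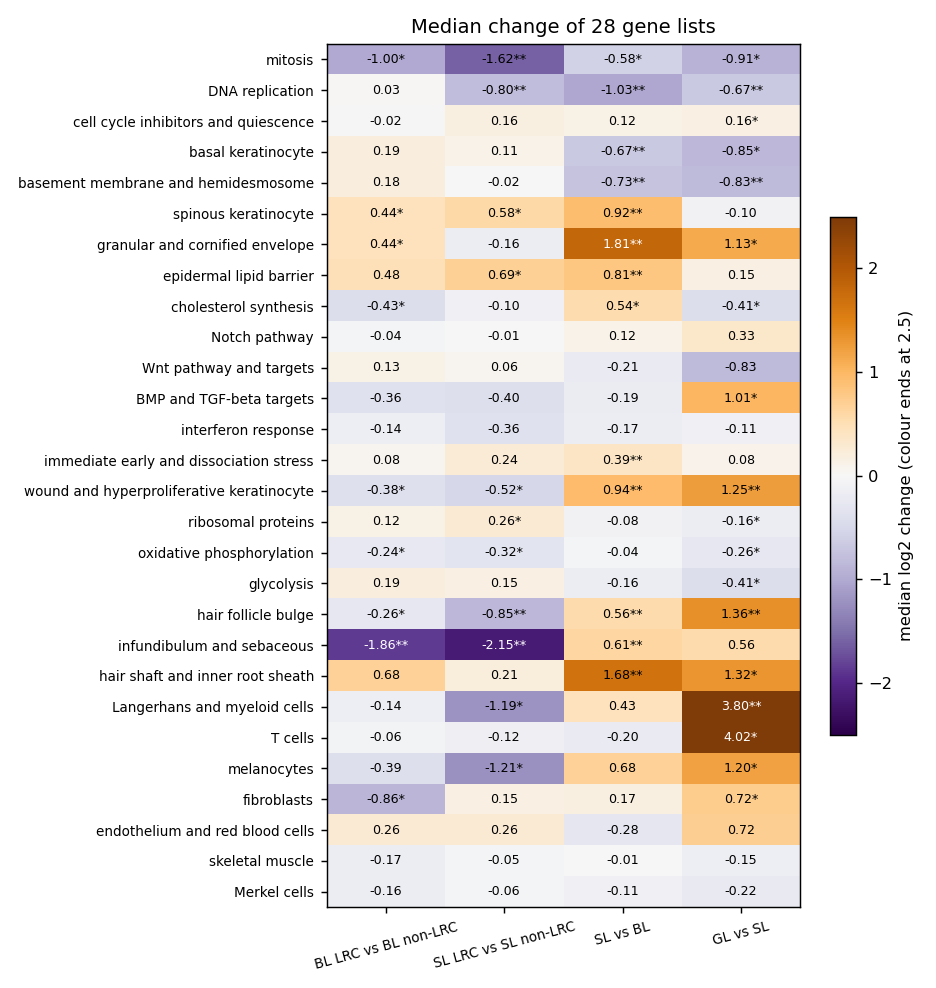
Median log2 change of the 28 gene lists (vertical) in 4 comparisons (horizontal), with colour ending at 2.5, a star for lists past the preset test and a second star where the estimated correlation also passed. The immune lists in GL vs SL reach 3.80 and 4.02, and the infundibulum and sebaceous list falls in LRCs of both layers.

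**Figure D4:**
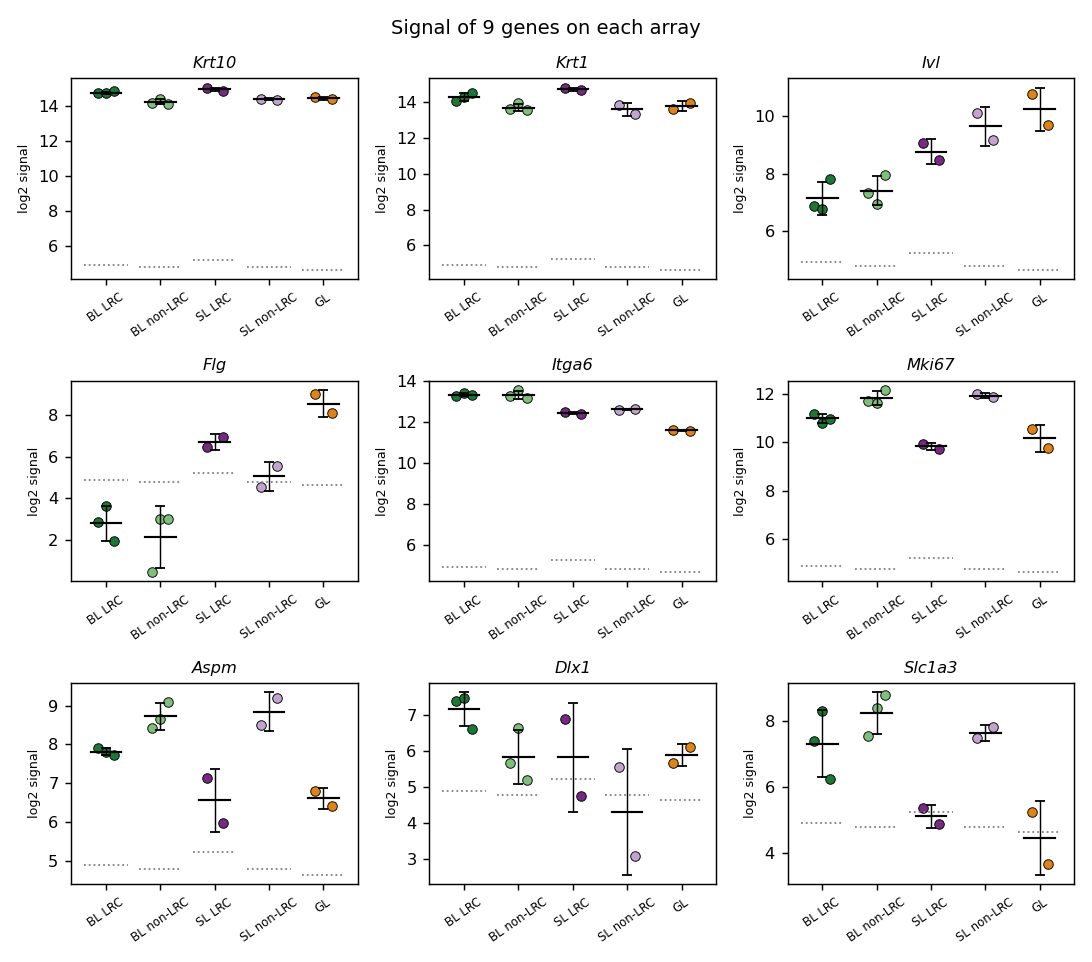
Log2 intensity of 9 keratinocyte and cell-cycle genes per array (points), with group means and SD (bars) and the background floor (dotted). Ivl is higher in SL than in BL by 1.94 log2 units, Itga6 lower by 0.82, and Mki67 is lower in SL LRCs by 2.09.

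**Figure D5:**
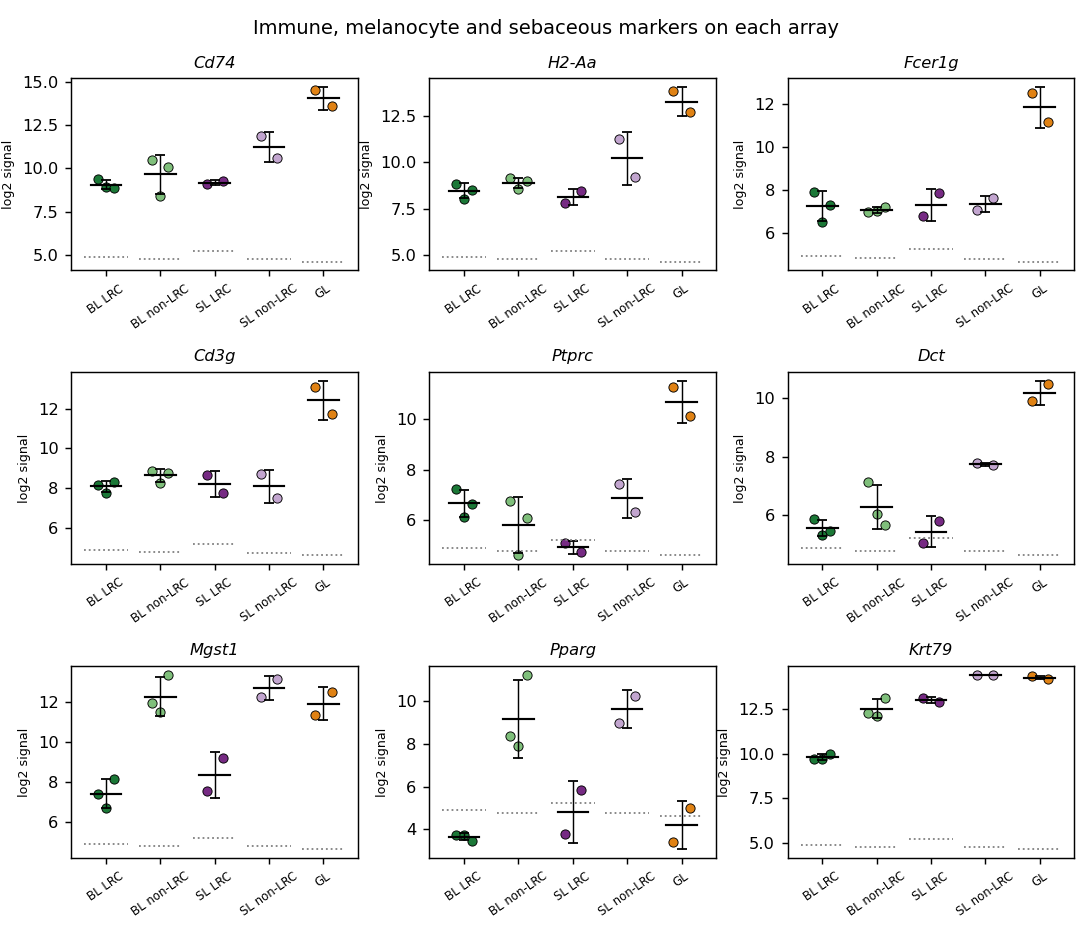
Log2 intensity of 9 immune, melanocyte and sebaceous markers in the same layout. Cd74 averages 14.0 in GL against 9.07 in BL LRC, and Mgst1 averages 7.41 in BL LRC against 12.3 in BL non-LRC.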

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

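In this part, the tests of the array set, of label retention shared with BL, of the share of immune markers and of the share of sebaceous markers were chosen only after the result was seen. Intervals are over genes and hold no spread between arrays.

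By the list test on the interaction (SL minus BL) with the preset correlation, 8 of 28 gene lists passed in their LRC minus non-LRC change. Of these 8, 1 also passed with fry and 1 with an estimated correlation. DNA replication alone kept its call in all 10 fits without 1 array. DNA replication genes were lower in LRCs of SL relative to BL by a median of -0.75 log2 units, which held with an estimated correlation (adjusted p = 0.0262) and with the array-set term (adjusted p = 4e-09). Mitosis genes also had a median of -0.75, with an adjusted p of 0.468 with an estimated correlation. Bulge genes had a median of -0.53 (adjusted p = 0.347 with an estimated correlation). Lipid barrier genes had a median of 0.51 (adjusted p = 0.347 with an estimated correlation, 0.315 with the set term). Cholesterol synthesis genes had a median of 0.44 (adjusted p = 0.496 and 0.111). Ribosomal protein genes had a median of 0.13 (adjusted p = 0.727 and 0.904). Myeloid genes had a median of -1.10 (adjusted p = 0.468 and 0.180). Melanocyte genes had a median of -1.13 (adjusted p = 0.347 and 0.315). Beyond the gene measurements, BioB control signal was 6.72-fold lower on 4 of the arrays than on the other 8.

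The first pattern is the 763 genes that differ between SL LRC and SL non-LRC, where the low-BioB arrays are exactly the non-LRC arrays. The same array difference inside BL, signed by the SL calls, had a median of 0.0681 log2 units (95% interval 0.0325 to 0.0914), under the bound of 0.418 that is 25% of the SL change, which argues against the array set as the whole cause. In BL the set coincides with the Y-linked signal, so this value holds both differences at once and would miss 2 that cancel. The label effect of BL, signed the same way, had a median of 0.673 (0.624 to 0.720). Genes called in SL thus leaned the same way in BL, by less than the median SL change of 1.67 for these calls. More sebaceous or infundibular cells among non-LRCs, taken up below, could also give a shared difference. The array set remains confounded with label retention for single SL genes, of which 270 of 763 stayed past the threshold with the set term.

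The second pattern is the immune signal of GL. The 28 myeloid and T-cell markers above background had a median of 3.91 log2 units (3.47 to 4.30) in GL over SL, while Cd74 and H2-Aa reached 14.0 and 13.3 in GL. A lower share of keratinocytes that raises every other cell type alike was weighed by 38 markers of melanocytes, fibroblasts, endothelium and Merkel cells. Their median was 0.749 (0.390 to 1.34). This cannot decide the question, since a type scarcely present in the fractions could not rise. Of these lists, Dct, Tyrp1 and Vim were called higher in GL and the other members were not called. The array set is argued against by the median of 4.29 (3.95 to 4.56) on high-BioB arrays alone. A larger number of Langerhans cells and epidermal T cells in the sorted GL fraction may be the source, as a hypothesis that a gate against CD45 would test, yet the share of 92.9% of markers higher in GL follows from the calls themselves (22 of 30) and decides nothing. Of 30 such markers measured, 15 were also above background on all 4 SL arrays. Immune cells in the SL fractions could give that signal too, so it does not tell cell number from a change of expression within cells. Both stay open.

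The third pattern is the sebaceous and infundibular signal that is lower in BL LRCs. A lower share of interfollicular keratinocytes among non-LRCs that raises every other cell type alike was weighed by 66 markers of other types. Their median was -0.311 (-0.551 to -0.0649), against -1.86 (-2.91 to -1.21) for 15 sebaceous and infundibular markers. This argues against it only for cell types present in the fractions, since a type scarcely present could not rise. On high-BioB arrays alone the median was -2.51 (-3.00 to -1.22). Its sign could not turn, since 12 of the 15 markers were called lower and no called BL gene overlapped between the groups. The array sets are balanced between the BL groups, so this value adds no test of them. More sebaceous or infundibular cells among non-LRCs may be the source, yet the share of 93.3% of markers lower in LRCs follows from the calls themselves (12 of 15) and decides nothing. Mgst1 averaged 7.41 in BL LRC and 12.3 in BL non-LRC and Scd1 12.6 and 13.7, and 10 of the 15 markers were above background on all 3 BL LRC arrays, with 1 also in another list. Sorting apart the upper follicle, for instance by LRIG1, would remove such cells.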

How the results depend on the processing

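The array-set term, the high-BioB arrays alone and the term for Y-linked signal are the tests chosen here only after the result was seen.

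Among settings of the statistical model, without the mean-variance trend 72 genes passed in BL, 150 in SL, 374 in SL vs BL, 713 in GL vs SL and 2 in the interaction (Gm15408 and Peg10). Fitting only the groups compared gave 183 in BL, and a 2-fold minimum gave 505 in SL vs BL. With an estimated correlation 22 list tests passed against 59. The cause was not tested.

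Among scalings and choices of probe set, centring arrays on medians gave 446 genes in BL, with Krt5 at -0.0033, Krt14 at -0.14, Krt15 at -0.059 and Itga6 at -0.23 there, Krt5 at -0.022 in SL and Krt5 at -0.071 in GL vs SL, each with the opposite sign to the main value. Quantile normalisation turned Krt14 to -0.043 in BL, and Slc1a3 to 0.39, Krt5 to -0.10 and Krt15 to -0.013 in SL. The probe set of highest mean was chosen again after it, so a value there may come from another probe set. The probe set of highest variance turned Slc1a3 to 0.72 in BL and Trp63 to 0.68 in GL vs SL, gave 2 interaction genes (Krt6a and Tpm2) and moved the correlation of the layer effects from 0.38 to 0.255. The mean of all probe sets turned Trp63 to 0.059 in GL vs SL and gave 2 interaction genes (Pfn2 and Tpm2). Leaving out the lower 50% of genes gave a correlation of 0.525 and an offset of 32 gave 0.446. Among called genes, the sign was kept with the probe set of highest variance in 272 of 279 in BL, 715 of 763 in SL, 871 of 915 in SL vs BL and 1446 of 1510 in GL vs SL. Those that turned include Mcm3 in GL vs SL (0.29) and Cdkn1b in SL (0.017). The cause of these moves was not tested.

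The array-set term gave 320 genes in SL, 1144 in GL vs SL, 5 in the interaction and a layer correlation of 0.264. Of those 5, Eif2s3y, Kdm5d and Uty are Y-linked, with Glul and Shmt1 the others, so the term carries the sex-linked difference of the BL arrays into SL, where there is none. A term for Y-linked signal instead gave 333 genes in BL, 997 in SL, 939 in SL vs BL and 1768 in GL vs SL, with 735 of 915 layer calls kept, a layer correlation of 0.416, and 5 interaction genes (Ctsl, Glul, Mcm5, Tpm1 and Tpm2). The high-BioB arrays alone gave 136 genes in BL and 282 in SL vs BL, with Aspm at 0.046 and Mki67 at 0.32 in GL vs SL, of opposite sign. Flg in BL also took another sign there (-0.25), and without BL non-LRC 1 (-0.21, against up to 1.08 in the other such fits), yet it was at or under background on all BL arrays, so its sign has no meaning.

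Leaving out 1 array at a time gave 131 to 288 genes in BL, 209 to 481 in SL, 529 to 985 in SL vs BL, 575 to 1227 in GL vs SL, 0 to 6 in the interaction and a layer correlation of 0.303 to 0.387. The counts that moved by more than 1.5 times were 169 without BL LRC 2, 149 without BL LRC 3 and 131 without BL non-LRC 3 in BL. In SL they were 300 without SL LRC 1, 410 without SL LRC 2, 481 without SL non-LRC 1 and 209 without SL non-LRC 2. In SL vs BL they were 605 without SL LRC 2 and 529 without SL non-LRC 1, and in GL vs SL 575 without GL 1 and 890 without GL 2. The interaction gave 1 without BL LRC 3, 3 without BL non-LRC 1, 6 without BL non-LRC 3, 1 without SL LRC 2 and 1 without SL non-LRC 2. Signs turned in BL for Ivl (-0.59 to 0.015, the latter without BL non-LRC 3) and Itga6 (-0.075 to 0.13, with -0.041 without BL LRC 2, -0.022 without BL non-LRC 1 and -0.075 without BL non-LRC 3). In SL the sign turned for Lor (-1.09 to 0.90, with 0.23 without SL LRC 2 and 0.90 without SL non-LRC 1). Where 1 array of a group is left, it is assumed to vary like the other groups.

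Replicate numbers were checked for pairing. Same-numbered BL samples correlated at 0.111, 0.0544 and 0.0643 over all genes and SL samples at -0.019, short of the 0.1 required of every pair, so no pairing was used. Over the upper 50% of genes, chosen after blocked counts were seen, they reached 0.425, 0.269 and 0.231 (SL 0.0606). Each BL sample correlated best with its own number, and number 1 coincides with low BioB and missing Y-linked signal. A replicate block gave 362 genes in BL, 906 in SL, 959 in SL vs BL and 1644 in GL vs SL, with 4 in the interaction (Ctsl, Mcm5, Tpm1 and Tpm2) and a layer correlation of 0.443. With it Mki67 would pass in BL (adjusted p = 0.021) and in GL vs SL (0.0252), Krt5 in SL vs BL (0.033) and Ivl in GL vs SL (0.0464). Nccrp1 in BL (0.0614), C8b in SL (0.0517) and E2f7 and Anln in SL vs BL (0.0504 and 0.130), among others, would lose their calls.

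Signal over background limits what can be seen, since only 68.5% to 78.4% of genes lay above the floor of an array.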

Other observations

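In this part the array-set term and the splits of the SL side in GL vs SL were chosen after the result was seen. The genes named are those of the lists and of the set named in advance.

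The sample labels were weighed by moving arrays between groups. Between SL and BL, the real labels called 915 genes. The highest of the other splits, made within LRC and within non-LRC arrays, called 76. Of 100 splits 1, the real one, reached the real count, which argues against a random split of these arrays. It does not exclude chance, since the other splits count the layer difference as spread, which lowers their counts. The arrays may also not be separate animals. In BL the real labels called 279 genes and the highest other split 0, with 1 of 10 reaching the real count, and these splits are too few to exclude chance.

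Members of the Notch pathway changed in both directions between BL and SL, and the list as a whole did not pass in any comparison. From BL to SL the target Nrarp rose by 1.07 ± 0.17 (SE, n = 4 and 6, adjusted p = 0.000771), with Notch2 also higher, while the ligand Jag2 (-0.89 ± 0.15, adjusted p = 0.00172) and the modifier Lfng (-1.20 ± 0.22) fell. From SL to GL, Jag2 (-2.23 ± 0.21, adjusted p = 5.53e-06) and the ligand Dll1 (-1.998 ± 0.33) fell. The list test gave adjusted p of 0.443 in BL, 0.811 in SL, 0.358 in SL vs BL and 0.55 in GL vs SL.

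Wnt pathway genes had 4 higher and 8 lower of 24 in GL vs SL, with a median of -0.83 and an adjusted p of 0.0531 for the list. Wnt4 (-1.50 ± 0.18, adjusted p = 7.79e-05), Apcdd1 (-1.05 ± 0.14), Axin2 (-1.18 ± 0.17) and Wnt10a (-3.15 ± 0.50) were lower there. Lgr6, a receptor found in epidermal stem cells, fell by 1.13 ± 0.25 from BL to SL. In the label comparisons the list had 0 of 24 called in BL, and 1 higher and 2 lower in SL.

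Cell cycle inhibitors passed as a list in GL vs SL with the preset correlation, though not with an estimated correlation (adjusted p = 0.0968) or in 2 of 6 fits without 1 array (highest 0.061). From BL to SL the list had an adjusted p of 0.0588. Cdkn1a rose by 1.34 ± 0.13 from BL to SL (adjusted p = 7.56e-06) and Cdkn2b by 1.38 ± 0.23 (adjusted p = 0.00127). In SL LRCs Cdkn2b was at 1.42 ± 0.35 and Cdkn1b at -0.68 ± 0.17, calls lost with the array-set term (adjusted p = 0.242 and 0.279), and in BL LRCs 0 of 19 passed. The immediate early gene Egr2 fell in LRCs of both layers, by 3.22 ± 0.25 in BL (adjusted p = 2.66e-06) and by 2.31 ± 0.30 in SL, and rose by 1.71 ± 0.20 from BL to SL.

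In BL LRCs, Igfbp2 of the basal list (-4.23 ± 0.57) and Nid1 of the basement membrane list (at least 8.59-fold lower) fell while the other members did not pass, and Fa2h of the lipid list fell by 4.55 ± 0.60 while Acer1 and Elovl4 rose, 2 calls lost with arrays centred on their medians. For the basal and basement membrane lists the median in BL was 0.19 and 0.18 and the mean -0.05 and -0.11, with an upward test that did not pass, and centring on medians turned the medians to -0.048 and -0.059. In GL vs SL, lipid barrier genes had 3 lower, a median of 0.15 and a downward test (adjusted p = 0.781). Their median was -0.21 against SL LRC (1 higher, 6 lower) and 0.57 against SL non-LRC (0 higher, 2 lower). Spinous genes had 1 higher in GL vs SL, Prdm1, and infundibulum and sebaceous genes 2 higher and 2 lower, with Pparg and Scd1 (-1.75) among the lower. Both directions depended on the SL side. Infundibulum and sebaceous genes had 7 higher and 1 lower against SL LRC (median 1.46), and 0 higher and 3 lower against SL non-LRC (-0.59). Spinous genes had 2 higher and 6 lower against SL LRC (-0.46), and 2 higher and 0 lower against SL non-LRC (0.30).

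Interferon response genes had 0 of 21 called in BL, SL vs BL and GL vs SL and 1 higher in SL LRCs. Endothelial and red blood cell genes (13), skeletal muscle genes (16) and Merkel cell genes (13) had 0 called in all 4 comparisons. T-cell genes had 0 of 15 called in either label comparison, and 1 lower, Thy1 (-1.39 ± 0.31), from BL to SL.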
